A study of Mus musculus with 4 samples.

How the data were processed

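Gene expression was measured in mouse CD4+ T cells on 4 one-colour Agilent arrays, 2 from wild-type cells and 2 from miR-155 knockout cells. Per the labels' protocols, the cells were grown with antibodies to CD3e and CD28 together with TGF-beta and IL-6, the conditions that direct T helper 17 (Th17) differentiation, and were then sorted by flow cytometry for CD4 and for a red fluorescent reporter of IL-17F. Total RNA was extracted with a Qiagen column kit and labelled with Cy3, per the labels' protocols. The series' design text calls the arrays biological replicates. No label ties an array to an animal, a culture or a day, so the p-values measure the spread between these samples, part of which may be technical.

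The authors deposited 1 scanner output per array, made with Agilent Feature Extraction 10.5.1.1, per the file headers. Its processed signal is a linear intensity after background subtraction and, per the file headers, spatial detrending. The scanner outputs also hold, per the file headers, the fitted multiplicative detrending surface at each spot, a linear ratio. Set against the other columns, it was the ratio of background-subtracted to processed signal wherever it had been applied. The authors also deposited a matrix of log2 values, whose processing steps are not given in the sources used here. Set against the log2 processed signal of the same array, each column of that matrix differed by 1 constant, within 0.001 for 99.4% to 99.5% of probes. All 4 columns had a median of 5.54. Scale, centring and direction of the matrix were thereby settled, and its values were used as an alternative only. All arrays lay on 1 slide and were scanned once, so no slide or scan term could be fitted. The wild-type arrays were in slide row 1 and the knockout arrays in slide row 2, so slide row and genotype cannot be told apart.

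The depth of an array is set by its signal over background, and the number of arrays limits the precision. Between 63.5% and 69.8% of spots were well above background on each array, and no spot was saturated. The median processed signal lay between 45.6 and 57.6. Knockout array 1 was less even than the others. Its fitted multiplicative surface had an SD of 0.157, against 0.0498 to 0.0557 on the other 3 arrays. Division by the surface gave the processed signal at 0.799% of its non-control spots well above background, against 100% on the others. Nearly all such spots of knockout array 1 thus lacked the multiplicative detrending. Replicate spike-in probes had a coefficient of variation of 15.3% on that array and of 3.37% to 4.04% on the others. In 2 corner blocks at the right edge of every array (columns from 139, rows up to 52 or from 311), probes bright on 3 arrays were over 8-fold dimmer on the fourth. There were 147 such probes on knockout array 1, 27 on wild-type array 2, 4 on wild-type array 1 and 0 on knockout array 2. These blocks held the probes of 1006 tested genes, 5.25% of the total.

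The signals were read with pandas 2.3.3 in Python 3.11.15. Control spots and spots flagged as outliers were left out, spots of the same probe were averaged, and log2 processed signals were shifted by each array's 75th percentile. The 55681 probes were named through RefSeq's table for mouse assembly GRCm38.p6, used for names and neighbours only. Of these probes, 26762 matched by accession, 3819 by symbol and 639 by synonym, and 24461 kept the name in the files. Probe positions are those in the files, on mm9. Features with a gene or transcript name (35944 probes, 26680 names) were analysed as genes. The 16194 probes of 4610 lincRNA regions and 3543 unnamed probes were kept apart, a choice made once the names had been seen and before any test was run. A probe was tested if it was well above background on both arrays of at least 1 genotype, and each gene was represented by the probe with the highest mean. This left 19151 genes. Genes with several probes are given by that probe, and disagreement between probes is stated where a named gene showed it.

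Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 2.16 prior degrees of freedom. All differences are log2 knockout minus wild type. A gene not well above background on both arrays of a genotype is given as at least N-fold: the mean of the brighter genotype against, per array of the dimmer one, the higher of the probe's own signal and the lowest signal well above background. No such fold is given where it would be under 1.

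The tests, the 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named 11 genes tied to miR-155, IL-17 and IL-23 biology, the 12 genes of each direction with the largest fold change past the threshold (or, failing that, the smallest p), both knockout arrays lying beyond both wild-type arrays and the name in the files being a gene symbol (no clone, model, transcript or accession name), and up to 4 members of each list with the smallest p. Of the 11 genes, 1 is not reported here, and of the list members those not needed as examples are left to the counts. The lists covered Th17 transcription factors, Th17 cytokines and receptors, IL-23, IL-12 and IL-1 family receptor signalling, pathogenic and non-pathogenic Th17 signatures, Th1, Th2, Treg, Tfh, naive and memory T cells, cytotoxic effectors, cell cycle, glycolysis and hypoxia, cholesterol biosynthesis, type I interferon response, unfolded protein and amino acid stress, immediate early and heat shock genes, signalling inhibitors, TGF-beta, apoptosis and reported miR-155 targets. A further 5 lists held markers of T cells, of CD8, NK and gamma-delta T cells, of B cells, of macrophages and dendritic cells, and of neutrophils, mast cells and erythroid cells. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation, camera's p also rests on the 2 residual degrees of freedom, so few lists can pass.

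In a simulation of the comparison over 19151 genes with 200 of them changed, run 10 times per size, the limma test recovered 0% of changes of log2 size 1, 65.0% of size 2 and 88.1% of size 3. In 10 simulations with no change, camera called 0 of 26 lists in any run. Every simulated gene varied independently of the others. These runs therefore cannot show how often camera calls lists whose genes vary together.

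The alternatives were median and quantile scaling, normexp background correction with an offset of 50 followed by quantile scaling, the authors' matrix, other filters on dim probes, the mean of a gene's probes, other priors, array weights, the replicate number as a block, leaving out each array, and other thresholds. Those added after seeing the data were a correction of knockout array 1 by its own surface, leaving out the corner blocks, and including all features. A planned test of genes with miR-155 seed sites was not run, since no untranslated region sequences were used here. No probe carried a name of the miR-155 host gene (0 of 55681), so the labels were not checked by the targeted gene. The array also measured 5 lincRNA regions within 20 kb of the probe of the neighbouring gene Mrpl39, which were not matched to the host gene and were fitted with the other lincRNA regions.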

Results

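The study compared Th17-polarised CD4+ T cells of 2 genotypes after sorting for IL-17F reporter expression, with 2 arrays of wild-type cells and 2 of miR-155 knockout cells. miR-155 is a microRNA that activated lymphocytes express. The series' title names the questions addressed, which are whether miR-155 bears on responsiveness to IL-23 and on effector gene expression in Th17 cells. Replicate arrays correlated across the 19151 tested genes with Pearson's r of 0.989 in wild type and 0.988 in the knockout, and r between genotypes was 0.981 to 0.989. Genes are not independent replicates, and these values describe the arrays only.

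Genes that mark the IL-17 program and the IL-23 receptor had lower signals in the knockout cells. Il17f, whose reporter was used for sorting, was at 3.73 ± 0.07 (SD, n = 2) in wild type and 1.72 ± 0.28 (SD, n = 2) in the knockout, a log2 difference of -2.01 ± 0.18 (SE) and a 4.02-fold lower signal. Il23r, the receptor subunit specific to IL-23, differed by -3.11 ± 0.38 (SE), Il17a, the founding cytokine of the lineage, by -3.17 ± 0.53 (SE), and Ccr6, a chemokine receptor of Th17 cells, by -2.40 ± 0.36 (SE). In the other direction, the type 2 cytokine genes Il5 and Il13 were higher by 3.58 ± 0.45 and 2.22 ± 0.51 (SE), and the granzyme genes Gzmc and Gzmb, which encode proteases of cytotoxic granules, by 1.85 ± 0.15 and 1.51 ± 0.13 (SE). Both knockout arrays lay beyond both wild-type arrays for each of these 8 genes, as they did for 47.8% of all genes tested. The rule for the 12 genes of each direction, which include Il17f, Gzmc and Gzmb, required this.

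No single gene passed the threshold over all genes tested. limma with Benjamini-Hochberg adjustment called 0 of 19151 genes at 0.05, with a smallest adjusted p of 0.254. At an unadjusted p under 0.05 there were 2174 genes, of which 1384 were higher and 790 lower in the knockout, where chance would give 958. At least 2-fold differences at that p numbered 299 higher and 94 lower. The groups did not overlap for 47.8% of genes, against 33.3% by chance. The split depended on scaling. With each array shifted by its median, the median of all genes moved to -0.14 and the split became 733 higher and 2211 lower, so that 24.9% of these genes were higher instead of 63.7%. That scaling moved every gene's difference by the same amount, so gene values and list medians under it are to be read against -0.14. Quantile scaling gave 51.6% higher. An exact permutation test of 1 gene with 2 against 2 arrays cannot give a two-sided p below 0.333.

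**Figure D1:**
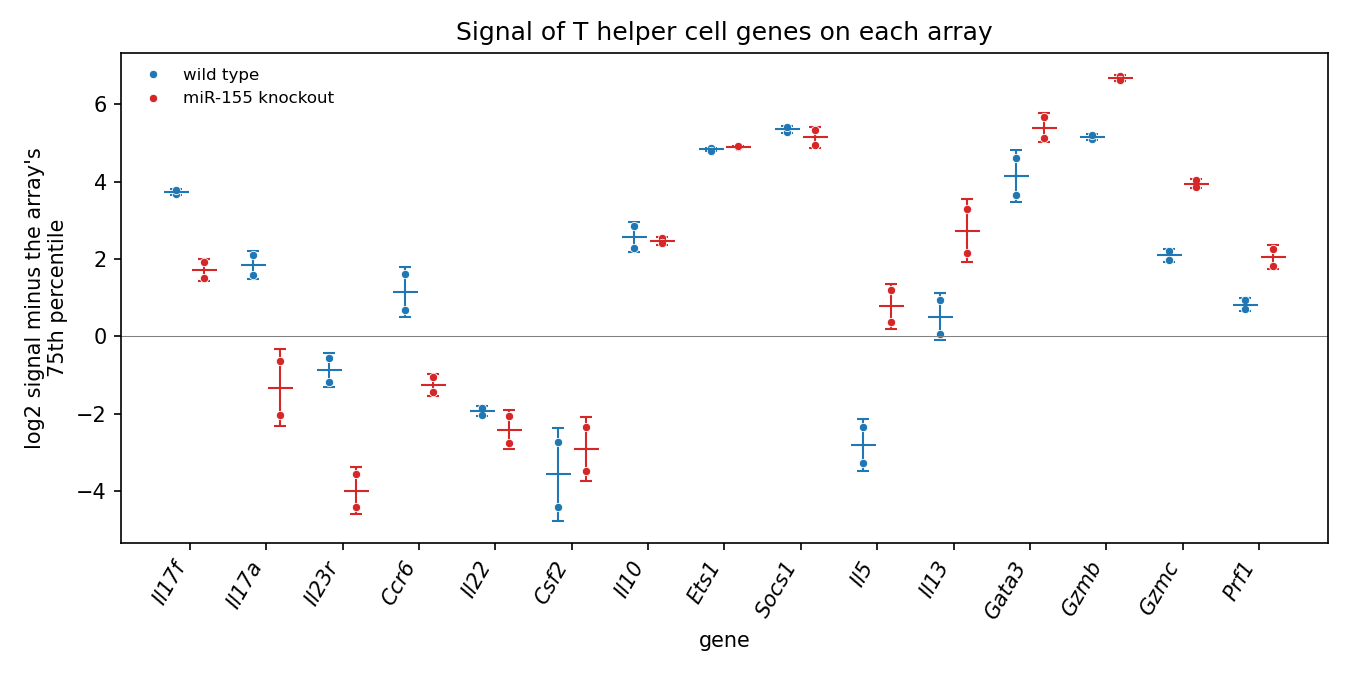
Signals of 15 T helper cell genes on each array, as log2 processed signal minus the array's 75th percentile (vertical axis) for each gene (horizontal axis), with blue for the 2 wild-type and red for the 2 miR-155 knockout arrays. Points are arrays, and bars show the mean and the SD, with Il17f at 3.73 in wild type and 1.72 in the knockout, and Il5 at -2.80 and 0.78.

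The list of Th17 cytokines, chemokines and receptors was lower as a group. Of its 19 tested members 13 had lower and 6 higher values, and 7 were lower at an unadjusted p under 0.05, with Il1r1, Lta and Il6ra joining the 4 genes above. Over all genes 0 members passed, and adjusted over the list alone 4 passed, namely Il17f, Il23r, Ccr6 and Il17a, all lower. The list's median was -0.23, and camera with its preset correlation gave an adjusted p of 0.00128. The call did not hold with the correlation estimated from these arrays, with adjusted p = 0.678 with an estimated correlation. Without wild-type replicate 2 the median was -0.38. Other cytokines of the list did not pass adjusted over the list alone. Lta had a difference of -0.64 ± 0.19 (SE), Il22 of -0.47 ± 0.28 (SE), Il10 of -0.10 ± 0.23 (SE), Il21 of 0.09 and Il9 of -0.12. Csf2, the GM-CSF gene, was at 0.66 ± 0.72 (SE), and its probe lay in a corner block. Without wild-type replicate 1, Csf2 and Il10 had the opposite sign, at -0.19 and 0.17.

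Il23r lay on mm9 chromosome 6, with its probe at 67372966 to 67373025. The Il17f probe spanned 20768074 to 20769419 on chromosome 1, and that of Il17a lay nearby at 20724404 to 20724463. Exon annotation on this build was not used here. In the list of IL-23, IL-12 and IL-1 family receptor signalling, which had 15 tested members, 0 passed over all genes and 2 were lower when adjusted over the list alone, Il23r and Il12rb2, the latter at -0.74 ± 0.13 (SE) for the IL-12 receptor chain. Il1r2, a decoy receptor for IL-1, was higher at 1.31 ± 0.30 (SE) with an unadjusted p of 0.0114, and the kinase genes Jak2 and Tyk2 had differences of 0.07 and 0.63. camera gave an adjusted p of 0.187 for this list.

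Th17 transcription factors differed by less than the cytokines. Ahr, a ligand-activated transcription factor, differed by -0.73, Nfkbiz by -1.12 and Rora by -0.59. They were among the 4 of 13 tested members that were lower at an unadjusted p under 0.05, and 0 passed over all genes or adjusted over the list alone. The median was -0.066 and camera's adjusted p was 0.187, and the list passed without wild-type replicate 2 (-0.16). Batf, Maf and Irf4 had values of 0.53, 0.13 and 0.18.

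The signatures that separate pathogenic from non-pathogenic Th17 cells did not pass. Of 16 pathogenic signature genes 12 had higher and 4 lower values, with a median of 0.25 and a camera adjusted p of 0.208. Gzmb was higher and Il23r lower when adjusted over the list alone, which are opposite directions within the list, and Casp1 was at 0.67 and Lag3 at 0.44. The 8 non-pathogenic genes had a median of -0.11 and an adjusted p of 0.472, with 0 passing adjusted over the list alone. Within that list Ahr was lower at an unadjusted p of 0.0126, and Il1rn, Cd5l and Ikzf3 had values of 0.46, -0.32 and 0.21.

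The Th2 list was higher as a group, with 12 of 12 tested members above wild type. Adjusted over the list alone, 4 were higher and 0 lower, namely Il5, Pparg, Il4 and Il13, and 0 passed over all genes. Il5 went from -2.80 ± 0.66 (SD, n = 2) to 0.78 ± 0.58 (SD, n = 2), an 11.9-fold higher signal. Gata3, the main Th2 transcription factor, was higher by 1.25 ± 0.40 (SE) at an unadjusted p of 0.0329. Il4 was higher by 1.36 ± 0.29 (SE), from a probe in a corner block. The list's median was 0.93 and camera's adjusted p was 9.27e-05. That call was lost with adjusted p = 0.678 with an estimated correlation, which was 0.539 for this list, and the median was 0.52 without wild-type replicate 2.

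Genes of cytotoxic granules were higher as well, with 12 of 13 tested members above wild type. Adjusted over the list alone, 4 were higher, namely Gzmc, Gzmb, Nkg7 and Prf1, the gene of perforin, at 1.23 ± 0.21 (SE), and 0 passed over all genes. Gzmb went from 5.16 ± 0.08 (SD, n = 2) to 6.67 ± 0.07 (SD, n = 2), a 2.86-fold higher signal. The exception was Ctla2b at -1.59, from a corner block. The median was 1.02 and camera's adjusted p was 0.000319, which became adjusted p = 0.678 with an estimated correlation, which was -0.082 for this list. The median was 0.47 without wild-type replicate 2. fry, which asks whether the members move one way on balance, gave an adjusted p of 0.00787. For the other lists called by camera with the preset correlation, fry did not pass. Its adjusted p ran from 0.207 (Th17 cytokines among them) to 0.460 (cell cycle), with 0.289 for Th2. Markers of other lymphocytes moved with the cytotoxic group. In the list of CD8, NK and gamma-delta T cell markers, Klra8 was higher by 1.66, Cd8a by 1.30 and Fcer1g by 0.94, which were 3 of 10 tested members higher when adjusted over the list alone, while Cd8b1, Klrd1, Klrk1 and Sox13 had values of -0.13, -0.47, -0.13 and -0.08. This list's adjusted p was 0.109 by camera and 0.0977 by fry, and it passed camera without wild-type replicate 1 (0.51).

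**Figure D2:**
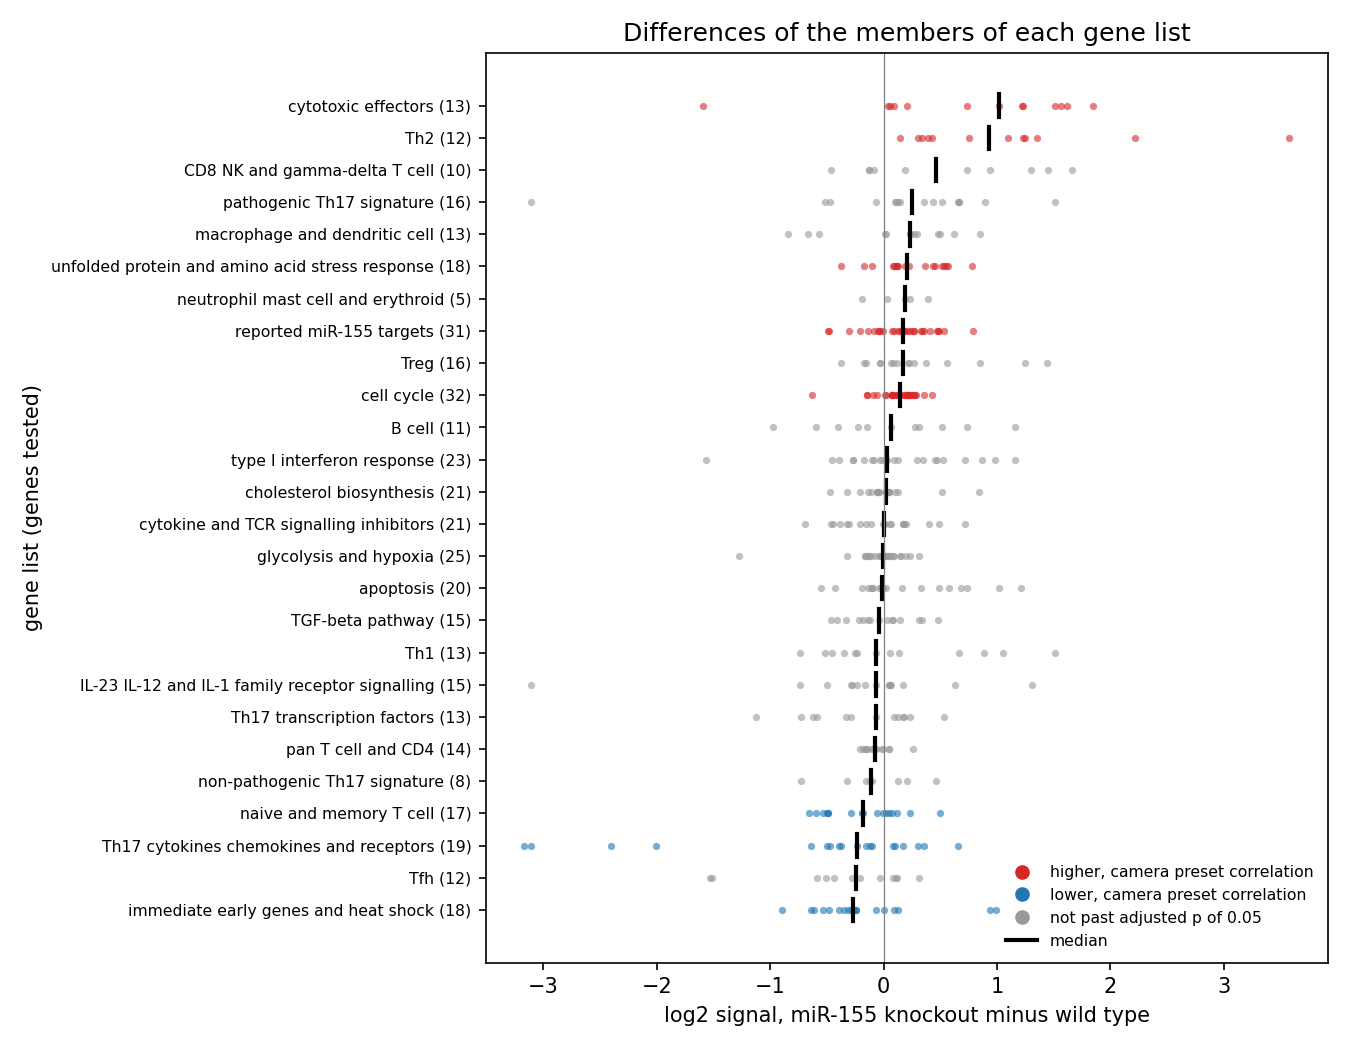
Log2 signal in the knockout minus wild type (horizontal axis) for each tested member of the 26 gene lists (vertical axis, with the number tested), sorted by list median. Points are genes, black ticks are medians, and colours mark lists past a camera adjusted p of 0.05 with the preset correlation (red higher, blue lower), with medians of 1.02 for cytotoxic effectors and 0.93 for Th2, while 0 lists passed with an estimated correlation.

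Naive and memory T cell genes were lower as a group. Tcf7, Foxp1, Cd27 and Bach2 were lower and Il7r, the IL-7 receptor gene, higher when adjusted over the list alone (4 lower, 1 higher, of 17 tested), and 0 passed over all genes. Tcf7, a transcription factor of naive and memory T cells, differed by -0.66 ± 0.13 (SE). The 5 tested probes of Foxp1 ranged from -0.60 to 0.35 and so disagreed in sign. The median was -0.19 and camera's adjusted p 0.0308, which became adjusted p = 0.699 with an estimated correlation. Leaving out wild-type replicate 2 or knockout replicate 1 ended the call, with medians of 0.014 and -0.096.

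Reported targets of miR-155 were slightly higher as a group. Of 31 tested members 21 had higher values, 7 were higher and 1 lower at an unadjusted p under 0.05, and 0 passed over all genes or adjusted over the list alone. Ikbke was at 0.53, Inpp5d (the phosphatase SHIP1) at 0.48, Bach1 at 0.48 and Zfp652 at 0.47, while S1pr1 was at -0.49. The Bach1 probe lies 3.01 Mb from that of Mrpl39, beside the miR-155 locus, so a local effect cannot be told apart for Bach1. The list's median was 0.17 and camera's adjusted p 0.0319, which became adjusted p = 0.699 with an estimated correlation and 0.110 with median scaling, where the median was 0.015 against -0.14 for all genes. The call also ended without wild-type replicate 2 (0.13), knockout replicate 1 (0.11) or knockout replicate 2 (0.25). Ets1, a transcription factor gene on the list of reported targets, was at 0.072 ± 0.12 (SE) from its brightest probe and 0.64 from its other, and the first turned to -0.089 with median scaling. Socs1, an inhibitor of cytokine signalling, was at -0.21 ± 0.18 (SE).

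Further lists moved by small amounts. Unfolded protein and amino acid stress genes were higher, with Trib3 at 0.53, Chac1 at 0.78, Pdia4 at 0.55 and Hspa5 at 0.36, a median of 0.21 and an adjusted p of 0.0214 by camera (adjusted p = 0.678 with an estimated correlation). Of its 18 tested genes 0 passed adjusted over the list alone. Cell cycle genes were higher in 27 of 32 tested members, with Cdc45 at 0.43 and Wee1 at 0.36, a median of 0.14 and an adjusted p of 0.0319 (adjusted p = 0.709 with an estimated correlation). With median scaling that median was -0.016 and the adjusted p 0.198, and the call ended without wild-type replicate 1 (0.071), wild-type replicate 2 (0.20) or knockout replicate 1 (0.086). Immediate early and heat shock genes were lower, with Egr3 at -0.64 (well above background on 1 of 2 knockout arrays), Nr4a2 at -0.90 and Dusp1 at -0.53 but the small heat shock gene Hspb1 at 0.99, a median of -0.27 and an adjusted p of 0.0268 (adjusted p = 0.678 with an estimated correlation). Adjusted over the list alone 0 of the 32 and 0 of the 18 passed. The stress and immediate early calls ended without wild-type replicate 2 (0.23 and -0.23) or knockout replicate 1 (0.22 and -0.41), and the latter median was -0.053 without knockout replicate 2. The immediate early call was also lost without the corner blocks, which hold Dusp1, Zfp36, Ier2, Fos and Egr2, where camera's adjusted p was 0.166, and Egr3 turned to 0.048 with knockout array 1 corrected.

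The other T helper lists did not pass camera. Th1 genes had a median of -0.064 (adjusted p of 0.746), with Gzmb higher and Il12rb2 lower when adjusted over the list alone, and with Ifng, the interferon-gamma gene, at 0.89 and Eomes at 1.05. Treg genes had a median of 0.17 (adjusted p of 0.165), with Itgae at 1.25, Nrp1 at 1.44 (well above background on 1 of 2 wild-type arrays), Ikzf2 at 0.85 and Foxp3 at 0.22. Tfh genes had a median of -0.24 (adjusted p of 0.0860), with Cd200 at -0.58 and Btla at -0.51, and with Pdcd1 at -1.53 from a corner block. Treg genes passed without wild-type replicate 1 (0.19) and Tfh genes without knockout replicate 2 (-0.18). For both Treg and Tfh 0 genes passed adjusted over the list alone.

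Metabolic and signalling lists did not pass either. Medians and camera's adjusted p were -0.0028 and 0.746 for glycolysis and hypoxia (Pkm at 0.32, Hk2 at -0.32), 0.018 and 0.733 for cholesterol biosynthesis (Acat2 at 0.84, Lss at 0.52), and 0.026 and 0.410 for the type I interferon response. In the interferon list Rtp4 was higher by 1.16 and Isg20 by 0.99, the 2 of 23 that passed adjusted over the list alone. The values were 0.0012 and 0.472 for signalling inhibitors (Dusp5 at 0.71, Dgkz at -0.44), -0.036 and 0.410 for the TGF-beta pathway (Smad4 at -0.46, Smad7 at -0.42), and -0.0098 and 0.650 for apoptosis (Tnfsf10 at 1.21, Fas at -0.43). Adjusted over the list alone 0 genes passed in these lists other than the interferon list. For Th1, apoptosis, glycolysis, cholesterol, inhibitor and B cell genes, the median, mean and tests differed in sign.

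Lists of pan T cell, B cell, myeloid and erythroid markers did not pass camera. Pan T cell genes had a median of -0.080 (camera adjusted p of 0.269), with Cd4 at -0.16 and Cd3e at -0.06. B cell markers had a median of 0.068 (0.844), with Ebf1 at -0.97 and Cd79b at 1.16 and Cd22 at -0.60 from corner blocks, and Cd22 turned to 0.071 with knockout array 1 corrected. Macrophage and dendritic cell markers had a median of 0.24 (0.269), with Cd74 at 0.48 and Cd14 at -0.67, and this list passed without wild-type replicate 1 (0.21) or knockout replicate 1 (0.34). Neutrophil, mast cell and erythroid markers had a median of 0.19 (0.733) over only 5 tested members, among them Hba-a1 at 0.23 and Camp, whose 2 tested probes disagreed in sign at 0.39 and -0.063. Of these genes 0 passed adjusted over the list alone.

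Among the genes named by a symbol in the files, the 12 with the smallest p that were higher in the knockout included 3 stefin genes of chromosome 16, which encode cysteine protease inhibitors. Stfa2 was higher by 2.51 ± 0.20 (SE), Stfa2l1 and Stfa1 both by 2.09. The others were Trgv2, a variable segment of the T cell receptor gamma chain, at 2.71 with 1 of 2 wild-type arrays well above background, Fgl2 at 1.96, Havcr2, the gene of the inhibitory receptor TIM-3, at 1.93, Lad1 at 1.71, Gpat2 at 1.69, and Gzmc and Gzmb. Sema3c was at least 3.80-fold and Olfr228 at least 2.32-fold higher, since neither was well above background on the wild-type arrays. The 12 lower ones, chosen in the same way, included Il17f, Syt11 at -1.37, Cyp1b1 at -1.37, Nebl at -1.28, Lgr4 at -1.20, Cyp4v3 at -1.12, Lamc3 at -1.10, Prg4 at -1.08 and Pabpc1l at -0.99. Npr3, Dcbld2 and Ly6g6e were well above background on both wild-type arrays and on 0 knockout arrays, at signals too low for a fold. None of these 24 genes passed limma's adjusted p of 0.05, with values of 0.254 for the first of each direction.

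The gene beside the deleted locus that the array measured was Mrpl39, a mitochondrial ribosomal protein gene that neighbours the miR-155 host gene in RefSeq's gene order. Its probe lay at 84718547 to 84718606 on mm9 chromosome 16. Mrpl39 was at 2.69 ± 0.05 (SD, n = 2) in wild type and 1.53 ± 0.17 (SD, n = 2) in the knockout, a difference of -1.16 ± 0.14 (SE) with a limma adjusted p of 0.254.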

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

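All tests in this part were chosen after the names of the array's features were seen. The lincRNA regions, which the comparison of genes does not use, were fitted on their own with limma. Of 3816 tested regions 1 passed a Benjamini-Hochberg adjusted p of 0.05, and 323 had an unadjusted p under 0.05, where chance would give 191. Of those 323, 264 were higher and 59 lower in the knockout.

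The region that passed stood out because it was above the level of the wild-type controls. It lies on mm9 chromosome 16 from 77670599 to 77691642 and had a fitted log2 difference of 4.28 ± 0.24 (SE), with an adjusted p of 0.0220. It was well above background on both knockout arrays and on 0 wild-type arrays, so that the fit rests on wild-type signals below background and the region is given as at least 5.81-fold higher. This bound was 5.96-fold with knockout array 1 corrected and 6.72-fold without that array. The named transcripts Mir99ahg and 9530003O04Rik lie in the same stretch of chromosome 16 and were at least 5.25-fold and at least 4.75-fold higher. Their probes lie at -7.22 and -7.06 Mb from that of Mrpl39, the neighbour of the miR-155 host gene. The region that passed is thus within 10 Mb of the targeted locus. An effect of DNA flanking that locus cannot be told apart here from an effect of losing miR-155.

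A signal on both knockout arrays and on no wild-type array was found for 3 lincRNA regions, while 26 showed the reverse, on both wild-type arrays and on no knockout array. The share of spots well above background was lowest on knockout array 2, at 63.5%.

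Within 20 kb of the Mrpl39 probe, beside the miR-155 locus, 5 tested lincRNA regions lay between 84702353 and 84710928 on mm9 chromosome 16. They were well above background on both arrays of both genotypes, with log2 differences of -0.96 to -0.40, which were -0.68 to -0.16 without knockout replicate 2 and -1.35 to -0.52 without knockout replicate 1. Of the 5, 2 were lower at an unadjusted p under 0.05 and 0 passed limma's adjusted p of 0.05, with a smallest value of 0.577. All 5 differences were negative with median and quantile scaling, with knockout array 1 corrected, without the corner blocks and without each array, and 0 of the 5 reached that unadjusted p without wild-type replicate 1 or knockout replicate 2. Some of the regions overlap one another, and whether any is part of the miR-155 host transcript was not settled here.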

How the results depend on the processing

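The correction of knockout array 1, the omission of the corner blocks and the inclusion of all features were chosen after seeing the data, and the other alternatives beforehand. limma called 0 genes under every scaling, filter, probe rule, prior, array weighting, block and threshold on the adjusted p that was run with all 4 arrays, with smallest adjusted p values from 0.0682 (normexp and quantile) to 0.508 (no filter on dim probes). Genes at an unadjusted p under 0.05 numbered 1710 to 2945 in these fits, and 1211 when a 1.5-fold difference was also asked for. Of 123 named genes 116 kept their direction under every alternative, and 0 passed an adjusted p of 0.05 under any run on all 4 arrays. Most of these genes were named for a small p or for groups that did not overlap. Where groups do not overlap, leaving out 1 array cannot turn the sign, so the count partly reflects that choice. The Th2, cytotoxic and Th17 cytokine lists kept their calls in 17 of 18 alternatives each. All 17 used the same preset correlation, so the 17 do not test that setting. The estimated correlation ended each call, but camera's p then also rested on the 2 residual degrees of freedom. Medians over the fits without 1 array were 0.52 to 1.34, 0.47 to 1.13 and -0.38 to -0.17, in that order. The cause of the changes below was not tested unless stated. The fits on 3 arrays assume that the lone array varies like those of the other genotype.

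Leaving out 1 array gave 0 to 50 genes called over the 4 fits, 0 to 27 of them higher and 0 to 49 lower. Without wild-type replicate 1 there were 27, all higher, and without knockout replicate 2 there were 50, of which 49 were lower and 1 higher. Probes in the dark corner blocks made up 26 of the 27 and 48 of the 50, since the array left alone in its genotype was then the one with dark spots. Genes at an unadjusted p under 0.05 numbered 1428 to 2195, those of them lower 396 to 976, with 396 and 397 without either wild-type array. List medians over the 4 fits ranged from -0.16 to 0.027 for Th17 transcription factors (called without wild-type replicate 2), 0.080 to 0.19 for Treg and 0.28 to 0.64 for CD8, NK and gamma-delta markers (both called without wild-type replicate 1), and -0.23 to -0.14 for Tfh (called without knockout replicate 2). Among lists called with all arrays, they ranged from -0.40 to 0.014 for naive and memory, 0.18 to 0.29 for unfolded protein and -0.41 to -0.053 for immediate early genes (each lost without wild-type replicate 2 or knockout replicate 1), 0.071 to 0.23 for cell cycle (kept only without knockout replicate 2) and 0.11 to 0.25 for miR-155 targets (kept only without wild-type replicate 1). The camera direction, never past the threshold in the main analysis, turned in at least 1 fit for non-pathogenic Th17 (-0.17 to 0.18), Th1 (-0.081 to -0.033), glycolysis (-0.036 to 0.013), apoptosis (-0.034 to 0.13), B cell (-0.028 to 0.12), macrophage (0.094 to 0.34, called without wild-type replicate 1 or knockout replicate 1) and neutrophil genes (-0.091 to 0.46). Single genes that changed sign were Csf2 (-0.19 to 1.51), Il10 (-0.38 to 0.17), Cd5l (-0.66 to 0.015) and Ltf (-0.091 to 0.47).

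With median scaling 733 genes were higher and 2211 lower at an unadjusted p under 0.05, and with the authors' values, which are scaled in the same way, 733 and 2212. Both ended the calls of naive and memory genes (-0.35), cell cycle (-0.016), immediate early genes (-0.43) and miR-155 targets (0.015), turned the camera direction of Th1 (-0.22) and B cell genes (-0.092), and gave Ets1 -0.089. Quantile scaling ended the naive and memory call (-0.17) and turned glycolysis (0.027), cholesterol (0.012), neutrophil genes (-0.0056) and Ltf (-0.0056). With normexp followed by quantile scaling 1218 genes were lower, the immediate early call ended (-0.18), and, as with quantile scaling alone, glycolysis (0.024), cholesterol (0.032), neutrophil genes (-0.0074) and Ltf (-0.0074) turned. Without a filter on dim probes Tfh was called (-0.24), cell cycle (0.15), unfolded protein (0.23) and miR-155 targets (0.18) were not, and apoptosis turned (-0.0098). The mean of a gene's probes called Tfh (-0.31) and not naive and memory genes (-0.19) or miR-155 targets (0.10). Correcting knockout array 1 ended the calls of naive and memory (-0.12), cell cycle (0.12) and immediate early genes (-0.24) and turned B cell genes (0.071), Egr3 (0.048) and Cd22 (0.071). Without the corner blocks the immediate early (-0.27) and miR-155 target (0.15) calls ended and the inhibitor list turned (0.0018).

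With an estimated correlation the 8 called lists, whose medians do not depend on it (Th17 cytokines -0.23, Th2 0.93, naive and memory -0.19, cytotoxic 1.02, cell cycle 0.14, unfolded protein 0.21, immediate early -0.27, miR-155 targets 0.17), had adjusted p of 0.678 to 0.709. The estimated correlation of the cytotoxic and immediate early lists, -0.082 and -0.052, was below the preset 0.01. A higher correlation thus does not account for the loss of these calls, and the few degrees of freedom limit the test for every list.

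Arrays with the same replicate number showed no shared deviation from their group means, with a correlation over genes of -0.000945. This value cannot show whether they shared an animal, a culture or a day. With the replicate number as a block limma called 0 genes, with 1710 at an unadjusted p under 0.05, of which 511 were lower. The cell cycle (0.14) and miR-155 target (0.17) lists were then not called, CD8, NK and gamma-delta markers were (0.46), and the B cell direction turned (0.068). The planned miR-155 seed site test with its alternatives, and the slide block, were not run. Signal over background limits dim genes, since 30.2% to 36.5% of spots were not well above background.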

Other observations

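The tests of one dilution factor and of the whole of chromosome 16 were chosen after their values had been seen, as were the Ly49 family, the receptor delta transcripts, the 10 Mb windows and the single genes named here. The other bounds were written after the patterns had been noticed but before the tested values were computed. The Ly49 family, natural killer receptors that some activated T cells also express, was higher throughout. For 11 of 11 tested Klra genes both knockout arrays lay above both wild-type arrays, and 10 had an unadjusted p under 0.05, with a median difference of 1.62. Klra12 was not well above background on either wild-type array, and with it at its bound the median was the same and the range 0.40 to 1.82. The median was 1.46 with median scaling and 1.51 with quantile scaling, and 11 of 11 were higher under both. Median scaling moves every gene by the same small amount, so it was no separate test of this family. limma's smallest adjusted p in the family was 0.254. The members are close paralogs, and signal shared between their probes was not separated.

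Other single genes far from wild type were Il6 at 3.37 ± 0.50 (SE), Il17rb, a receptor for IL-25, at 2.79 ± 0.69 (SE), Klrg1 at 1.95 ± 0.21 (SE) and Cxcr6 at 1.32 ± 0.41 (SE). Their limma adjusted p were 0.281, 0.337, 0.254 and 0.395. Il6 and Il17rb were well above background on 1 of the 2 wild-type arrays.

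T cell receptor gamma transcripts had higher signals in the knockout: of 9 tested, 8 were higher at an unadjusted p under 0.05, with a median of 1.79 that was 1.63 with median scaling and 1.69 without knockout array 1, and so were the 3 delta transcripts tested, delta variable 1 at 0.68, delta variable 5 at 1.29 and A630038E17Rik, whose probe lies between delta segments, at 1.86. A candidate explanation is gamma-delta T cells in the sorted sample, which would bring transcripts of both loci, although the gate on CD4 would remove most of them. Among their markers Zbtb16 was at 1.45, Cd163l1 at 1.12, Blk at 0.73 and Sox13 at -0.08, while Trdc was not tested here, and the markers' median lay 0.866 below that of the receptor transcripts, within the bound of 1 set for it. The prediction also asked that every tested marker be higher on both knockout arrays, and Sox13 was not. Sox13 was already well above background in wild type, which could hide a small share of such cells. The other markers were so too, and Zbtb16 rose from a similar wild-type level, -0.99 against -0.38 for Sox13. The delta values go with this source, but with 4 markers that do not move together it cannot be told apart from transcription of both receptor loci within CD4+ cells or from the genotype itself.

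The lower values of IL-17 lineage genes, 9 of 10 tested with a median of -1.06, may reflect fewer IL-17-producing cells among the sorted knockout cells, so that 1 dilution factor would apply to all. Uneven brightness of knockout array 1 as the whole cause is argued against by the median of -0.77 without that array and -0.68 with it corrected, both beyond the bound of -0.5. Under dilution by cells without Il17f, whose transcript the sort selects for, no gene should drop further than Il17f. If the diluting cells carried some Il17f, which was not measured, genes they lack could drop further by dilution alone. Il23r lay further below Il17f at -2.59 standard errors, combined from the errors of the 2 genes as if these were independent. Both genes were measured on the same arrays, so these standard errors and the p-values that follow ignore that pairing. Within an array, Il23r minus Il17f was -4.86 and -4.33 in wild type against -5.07 and -6.32 in the knockout. The one-sided p of the largest such drop, after Bonferroni correction over the 9 other genes, was 0.263, and 0.0298 without knockout array 1, where Il17a lay at -6.32 and Il23r at -4.64 standard errors, against 0.249 to 0.492 without each other array. Since that call rests on which array is left out, dilution cannot be told apart from lower transcription per cell on these 4 arrays, and an effect of the genotype stays open.

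Genes on chromosome 16, which carries the miR-155 locus, differed more often than others. Genes named above on this chromosome include Nfkbiz, Cd200 and Btla, and, within 10 Mb of the Mrpl39 probe, Bach1, Mir99ahg and 9530003O04Rik. Within 10 Mb of the Mrpl39 probe 17 of 107 genes (15.9%) had an unadjusted p under 0.05, against 11.3% on other chromosomes, with a one-sided Fisher's exact p of 0.0920, of 0.0919 with knockout array 1 corrected and of 0.440 without that array (11.2% against 10.4%), and the bound set for it, a p of 0.05 or more, was too loose to exclude flanking DNA, since the share's exact 95% interval of 9.54% to 24.2% holds both shares. Over the whole chromosome the share was 14.8%, the highest of 20 chromosomes, with a one-sided Fisher's exact p of 0.00528 that became 0.0630 without the 35 genes around the stefin cluster, and without these 0.0965 without knockout array 1, 0.00908 with it corrected and 0.000397 with median scaling. Over windows of 10 Mb the share ran from 6.20% of 129 genes at 10 to 20 Mb to 34.8% of 46 at 50 to 60 Mb, with 15.2% of 46 at 80 to 90 Mb, which holds Mrpl39. Strain-derived flanking DNA may contribute, but neighbouring genes are not independent, the chromosome was chosen after its values were seen, and the strain of either genotype is not given in the sources used here.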
